A study of Homo sapiens with 2 samples.

How the data were processed

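Small RNAs were compared between total lysate RNA and RNA recovered with endogenous LARP7 from HEK293 cells, with 1 library of each. Per the labels' protocols, cleared lysate was incubated with a rabbit anti-LARP7 serum on Protein A sepharose and washed at raised salt. RNA of the precipitate was released with proteinase K and phenol/chloroform, whereas the Input was extracted from the lysate with TRIzol. Adapters were ligated to the 3′ and 5′ ends, and the PCR products above the empty adapter dimers were cut from a gel. Ligation favours RNAs with free ends of a suitable kind and gel selection favours a range of lengths, so shares of reads are not shares of RNA molecules. The extraction method differs between the groups, and a control precipitate was not analysed here.

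The authors' deposited table holds whole-number read counts per annotated row for both libraries, not normalized. The submitters' processing notes name CASAVA 1.8.2, cutadapt 1.17, Bowtie2 2.3.4.1, R 3.3.3 and DESeq2 1.14.1 and the build GRCh38 (hg38), without their roles. The counting step, the annotation versions, the use of strand and the treatment of reads that map to several places are not given in the sources used here. The table has 31322 rows that mix several annotations: snoRNA, scaRNA, tRNA and rRNA gene names, repeat families, short names such as U1 or 7SK, and 29217 Ensembl transcript IDs. Rows named MIR are repeat families and were not read as microRNAs. The 2 rows that name only a strand were left out; they held 6 Input reads (0.000187%) and 1 IP read (2.82e-05%).

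The same reads can be counted in several rows. With a tolerance of 1 read in each library and at least 200 reads together, 29 rows repeated the counts of another row, and held 31.2% of the Input and 16.3% of the IP. Of these, 10 were Ensembl rows that repeat 5.8S rRNA rows. The counts do not show whether reads were shared among copies at random or counted for each copy, so sums over copies of a single RNA carry that doubt.

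Library totals were 3215228 reads (Input) and 3540774 reads (IP). A count of 0 allows up to 3 reads, which is 0.933 counts per 1000000 (CPM) in the Input and 0.847 in the IP. Ratios are of CPM, with exact 95% intervals from the conditional binomial (Clopper-Pearson), and shares have exact binomial (Clopper-Pearson) intervals. Log2 ratios add 0.5 reads to each library. A row counted as higher or lower where the ratio was at least 4-fold and its interval lay wholly beyond 1, among rows with at least 50 reads over both libraries. A ratio against 0 reads is given as a bound against 3 reads. A list's median log2 ratio was set against 10000 random lists of the same size, drawn from the other rows within 10 bins of mean abundance. With 1 library per group no test of IP against Input was run across rows; the closing section gives a permutation test of a different kind, of whether snoRNAs within the same gene have like ratios.

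The RNA lists were fixed before the data were examined, from textbook membership: 7SK, its copies, U6, the U6 genes known to be transcribed, the U6 guide snoRNAs, U3 with U8 and U13, imprinted snoRNAs, other box C/D snoRNAs, H/ACA snoRNAs, scaRNAs, U4 and U5, U1 and U2, the minor spliceosome, Y RNAs, vault RNAs, 5S, 7SL, RNase P and MRP, telomerase RNA, nuclear and mitochondrial tRNAs, microRNAs, and rRNA. The rows HY1, HY3, HY4 and HY5, older symbols of the Y RNAs, were taken for the Y RNA list. Rows with an Ensembl ID alone were not matched to any list. The report names every member past the filter of a list with at most 10 such members. For longer lists it names the 3 highest, the 3 lowest and the 2 most abundant among rows with at least 200 reads, and over all rows the 15 highest, the 10 lowest and the 10 most abundant of each library. Of those, rows with an Ensembl ID alone were limited to 2 higher and 2 lower. Other names are said to have been chosen after their values were seen.

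Positions and containing genes of snoRNAs and scaRNAs came from the RefSeq annotation of GRCh38.p14, the build of the processing notes; 337 of 337 names matched. The table gives gene spans without strand or exons.

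The analysis used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9, and R 4.3.3 with DESeq2 1.42.0 and edgeR 4.0.16 for scaling factors only. The rule for higher and lower rows was tested on simulated counts for the comparison of LARP7 IP with Input over 1012 rows, drawn from the means of the real libraries, with the 50 most abundant rows left unchanged. It called 100% of 50 rows made 8-fold higher, 97.4% of 39 made 8-fold lower, 96% of 50 made 5-fold higher and 90% of 40 made 5-fold lower. It called 0 of 833 unchanged rows, and the interval held the true ratio, allowing for the shift of the total, for 94.1% of these. The simulated libraries held counting error only, so these rates do not cover PCR, extraction or other differences between libraries. When changed rows were drawn from all rows, the abundant ones included, the total shifted by 1.03 on the log2 scale. The rule then called 38% of 50 rows made 8-fold higher and 0% of 50 made 5-fold higher, but 100% of the rows made 8-fold or 5-fold lower, over 919 rows. Ratios to the library total are therefore relative to the abundant RNAs, which is why alternatives to the total were run.

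Alternatives covered the library scaling (DESeq2 size factors, edgeR TMM, totals without 7SK and U6), the read filter (10 reads, 200 reads, a mean of 10 CPM, none), the size of the ratio (2-fold, 8-fold, no interval), the pseudocount (1 and 5 reads) and the matching of random lists. After the data were seen, totals with repeated rows counted once, totals without rRNA, and medians and percentiles with 0 reads at the floor were added. In the last of these, no reads were added to counts above 0.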

Results

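LARP7, a La-related protein and a stable part of the 7SK ribonucleoprotein, was immunoprecipitated at its endogenous level from HEK293 cells, a human embryonic kidney line, and the small RNAs recovered with it were sequenced. The comparison asked which small RNAs were enriched over the lysate the precipitate came from. It rested on 2 libraries, 1 from total lysate RNA (Input) and 1 from the LARP7 precipitate (IP), with 3215228 and 3540774 counted reads. Reads fell on 13277 rows of the count table in the Input and on 24893 in the IP. With 1 library of each kind, no difference between them has a replicate check, and no p-value is given for any. Brackets and ranges after a ratio are exact 95% counting intervals; they cover counting error only, since PCR reads without molecular identifiers are not independent molecules.

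Box C/D snoRNAs, which mostly guide 2′-O-methylation of RNA, made up 6.22% of the Input reads (6.20 to 6.25%) and 43.4% of the IP reads (43.3 to 43.4%), a 6.96-fold higher share. Box H/ACA snoRNAs, which guide pseudouridylation, had 0.0477% of the Input and 0.892% of the IP, 18.7-fold higher (17.8 to 19.7). Small Cajal body RNAs (scaRNAs), which guide modification of spliceosomal RNAs, had 0.0125% and 0.189%, 15.1-fold higher (13.7 to 16.8). Both sums leaned on few rows. SNORA80A and SNORA101B held 0.371% and 0.289% of the IP, and SCARNA22 and SCARNA20 held 0.112% and 0.0395%. In the other direction, the rRNA rows other than 5S held 32.6% of the Input and 18.8% of the IP, and the U1 and U2 rows held 0.859% and 0.175%. The share of nuclear tRNAs was 2.22% in the Input and 2.55% in the IP, an order that turned to 3.23% and 3.05% with repeated rows counted once.

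**Figure D1:**
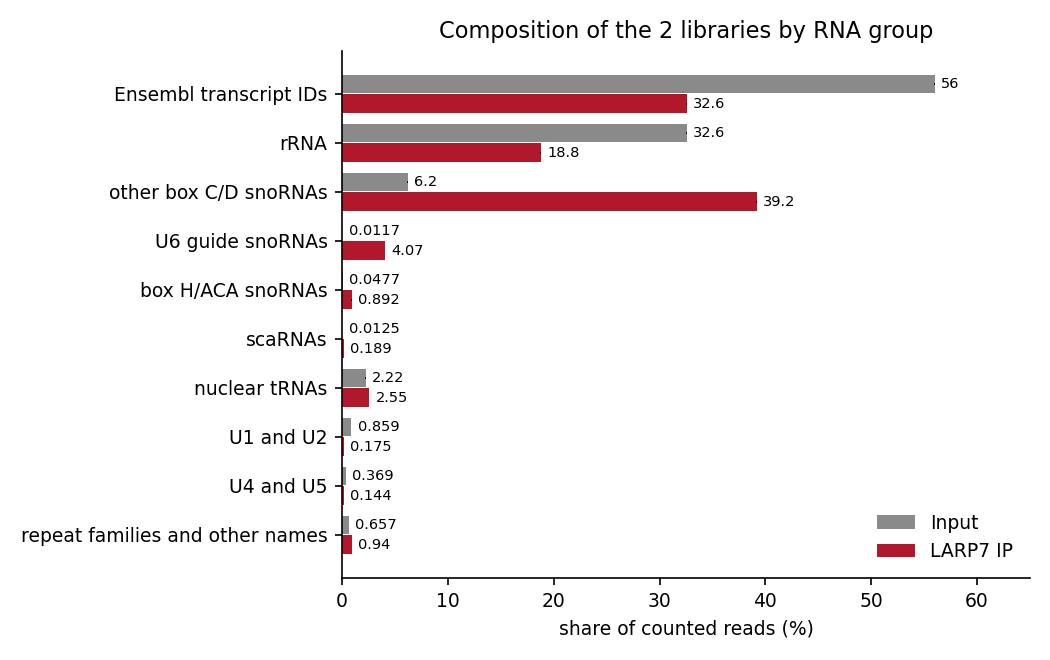
Share of counted reads (%) of each RNA group in the Input library (grey) and the LARP7 IP library (red), with exact 95% counting intervals as thin lines that are mostly narrower than the bar ends; the number is the share. Here other box C/D snoRNAs leave out the U6 guide snoRNAs, which went from 0.0117% to 4.07%, and rows that carry an Ensembl transcript ID, which went from 56.0% to 32.6%, are not named.

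Of 1031 rows with at least 50 reads over both libraries, 284 were at least 4-fold higher in the IP and 118 at least 4-fold lower, each with its interval beyond 1. The median row had a log2 ratio of 0.33, which was 0.014 with TMM factors and turned to -0.50 with the total taken without rRNA. The split depended on the library total: with the total taken without rRNA, an alternative chosen after the data were seen, 193 rows were higher and 228 lower.

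Among the fixed lists with over 1 row past the filter, the highest median ratio was that of the 6 box C/D snoRNAs that guide methylation of the spliceosomal U6 snRNA, all of which were at least 4-fold higher in the IP. Together they went from 376 to 144167 reads, 348-fold higher (315 to 386), and from 0.0117% to 4.07% of the library. SNORD8 had 296 Input reads and 138715 IP reads, 426-fold higher (380 to 479), and alone held 3.92% of the IP. SNORD94 had 8 and 3487 reads, 396-fold higher (201 to 918). SNORD9 had 0 Input reads, which allows up to 0.933 counts per 1000000 (CPM), and 156 IP reads, at least 47.2-fold higher against a floor of 3 Input reads. SNORD7 had 3 and 159 reads, 48.1-fold higher (16.2 to 236), SNORD67 had 3 and 126, 38.1-fold higher (12.8 to 187), and SNORD10 had 66 and 1524, 21.0-fold higher (16.4 to 27.3). Without SNORD8 the other 5 went from 80 to 5452 reads, 61.9-fold higher (49.6 to 78.2).

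In the GRCh38.p14 annotation SNORD8 lies on chromosome 14 from 21397293 to 21397401 and SNORD9 from 21392151 to 21392253, both within the span of CHD8, a chromatin remodeller gene. SNORD94 lies on chromosome 2 from 86135870 to 86136006 within PTCD3. SNORD7 lies on chromosome 17 from 35573657 to 35573753 within the non-coding gene SNHG30. SNORD10 lies on the same chromosome from 7576811 to 7576958 within EIF4A1, a translation initiation factor gene, and within the readthrough gene SENP3-EIF4A1. SNORD67 lies on chromosome 11 from 46762389 to 46762499 within CKAP5. Exon and intron positions inside these genes were not analysed here.

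The 147 box C/D snoRNAs past the read filter were ordered by ratio without added reads and with SNORD9 at its bound. The U6 guides held ranks 1 (SNORD8), 2 (SNORD94), 4 (SNORD7), 5 (SNORD9), 7 (SNORD67) and 15 (SNORD10). By Input reads SNORD8 ranked 52 of 147, and SNORD94 ranked 137. The median log2 ratio of the list was 6.76 with 0.5 reads added to each library, and 5.58 without added reads and with SNORD9 at its bound. As a description of these libraries, the value of 6.76 lay at percentile 100 of 10000 random lists matched on mean abundance, the highest of which had a median of 5.995. With 0 Input reads at the floor in the random lists too, 5.58 was again at percentile 100, against a highest random median of 5.27. Matched on Input abundance the percentile was 99.97, and the highest random median, 6.86, exceeded that of the list. Against box C/D snoRNAs alone it was 100, with 4.14 the highest random median.

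**Figure D2:**
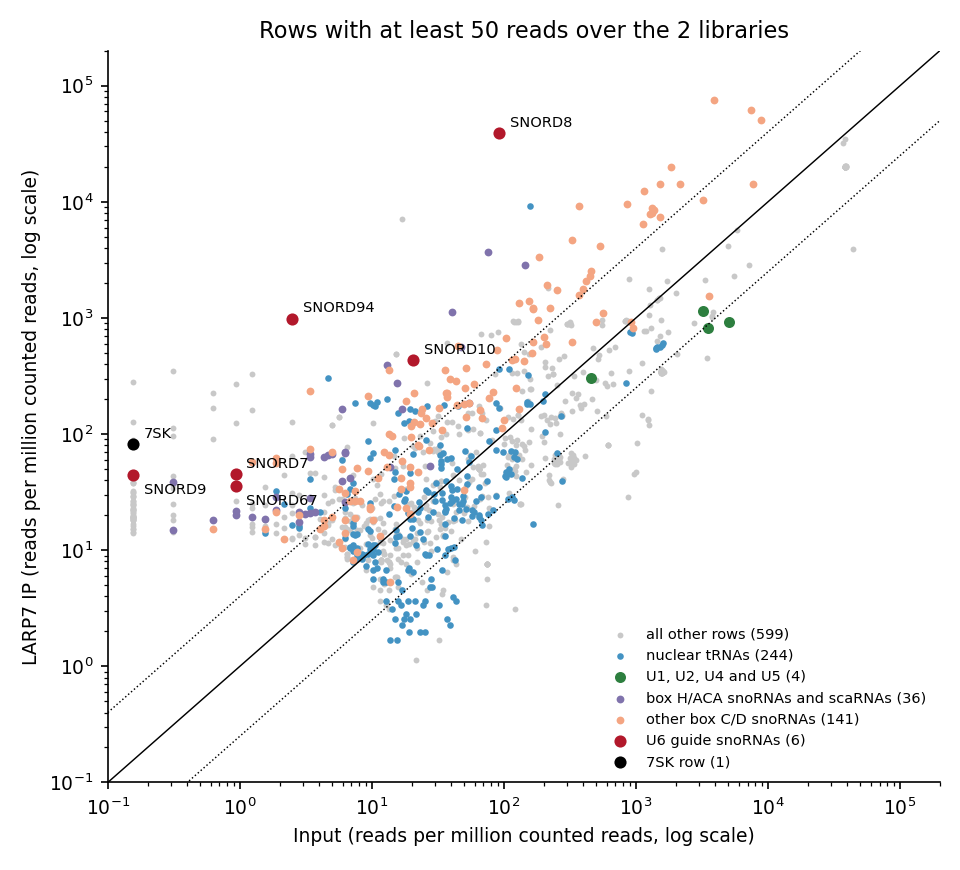
Counts per 1000000 counted reads in the Input (x axis) and the LARP7 IP (y axis), both on log scales, for the 1031 rows with at least 50 reads; each point is a row of the table, the solid line marks equal shares, the dotted lines mark 4-fold differences, and 0 reads are drawn at 0.5 reads. The 6 U6 guide snoRNAs (red), from 21.0-fold for SNORD10 to 426-fold for SNORD8, and the 7SK row (black) lie above the upper dotted line, while the U1 and U2 rows (green) lie below the lower one.

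The known RNA partner of LARP7 is 7SK, the scaffold that holds the elongation factor P-TEFb. The row named 7SK had 0 Input reads and 289 IP reads, at least 87.5-fold higher against the floor of 3 reads. Whether the rows with such short names (7SK, 7SLRNA, 5S, U1, U2, U4, U5, U6, HY1, HY3, HY4 and HY5) count the genes or their dispersed copies is not given in the sources used here. Their values are therefore those of the rows, not of the RNAs. Rows with an Ensembl ID alone were not matched to the RNA lists, so reads of these genes may lie there instead. The row named U6 had 12 and 18 reads, a ratio of 1.36 (0.621 to 3.10), so a difference was not detectable for this row at its depth, and nothing is said of U6 itself, since so few reads in total RNA leave open whether the row counts the U6 genes.

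Most other box C/D snoRNAs were also higher in the IP, but by less than the U6 guides. Of 136 such snoRNAs past the filter, 76 were at least 4-fold higher, 60 lay between and 0 were at least 4-fold lower, with a median of 4.81-fold (log2 2.27). SNORD45A, within RABGGTB on chromosome 1, had the most IP reads of any row: 12529 in the Input and 265013 in the IP, 19.2-fold higher (18.9 to 19.6). Its neighbour SNORD45C in the same gene was 8.35-fold higher (8.24 to 8.47) and SNORD44, within GAS5, was 5.64-fold higher (5.57 to 5.71). SNORD45A, SNORD45C, SNORD44 and SNORD8 together made up 22.6% of the IP, and the box C/D snoRNAs without them were still 4.94-fold higher. Among members with at least 200 reads, the highest ratios belonged to SNORD14C, within HSPA8, at 68.8-fold (38.3 to 138), SNORD16, within RPL4, at 46.3-fold (17.8 to 172) and SNORD14A, within RPS13, at 33.1-fold (14.98 to 91.3). At the other end SNORD136, within GNL3, was 2.34-fold lower in the IP (2.26 to 2.41), SNORD50B 1.52-fold lower (1.19 to 1.94) and SNORD31 1.167-fold lower (1.11 to 1.23).

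The list of U3, U8 and U13, snoRNAs of rRNA maturation with their own promoters, had 5 of 5 rows at least 4-fold higher, but 1 of 5 with the total taken without rRNA. Its median log2 ratio was 2.60, at percentile 94.78 of the matched random lists. SNORD13 (U13) was 10.7-fold higher (8.18 to 14.3), SNORD118 (U8) 6.77-fold (4.97 to 9.42), and the U3 copies SNORD3D, SNORD3C and SNORD3A 6.11-fold, 5.20-fold and 4.57-fold. U3 copies are near identical, so reads may be split among them, and their values are uncertain singly. The further U3 copies SNORD3B-1 and SNORD3B-2 fell outside the list as it was written and were counted among the other box C/D snoRNAs; named after their values were seen, they were 4.35-fold and 5.31-fold higher. Rows of the imprinted snoRNA clusters had 1 and 3 reads over 4 rows and were not compared.

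Of 120 box H/ACA snoRNA rows, 25 passed the filter, of which 24 were at least 4-fold higher, with a median of 11.9-fold (log2 3.58). Rows with few Input reads pass the filter only with far more IP reads, so the filter favours high ratios. With at least 10 reads, 61 rows had a median log2 ratio of 2.92. SNORA80A, within URB1, was 49.1-fold higher (43.3 to 56.0), from 243 to 13147 reads. SNORA71D was 27.6-fold higher (17.5 to 46.1) and SNORA101B 20.1-fold (18.3 to 22.1). The lowest among members with at least 200 reads were SNORA2C at 3.42-fold (2.89 to 4.06), SNORA64 at 9.79-fold and SNORA68 at 11.1-fold. Of 11 scaRNAs past the filter, from 27 rows, 9 were at least 4-fold higher, with a median log2 ratio of 3.81. The same limit holds here, since 22 scaRNA rows with at least 10 reads had a median of 2.99. SCARNA20, within USP32, was 30.2-fold higher (22.3 to 42.2), SCARNA22, within NSD2, 27.8-fold (23.3 to 33.3) and SCARNA26A 14.5-fold (8.44 to 26.9), while SCARNA3 at 3.82-fold and SCARNA15 at 1.93-fold (1.49 to 2.52) stayed under the 4-fold mark.

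The medians of all box C/D snoRNAs, H/ACA snoRNAs and scaRNAs lay 1.99, 3.25 and 3.47 log2 units above the median of all 1031 rows, a distance that no scaling changes. Their percentiles among matched random lists were 100, 100 and 99.96. With the total taken without rRNA, 39 of 147 box C/D snoRNAs, 18 of 25 H/ACA snoRNAs and 8 of 11 scaRNAs were at least 4-fold higher, and 2 box C/D snoRNAs were at least 4-fold lower.

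**Figure D3:**
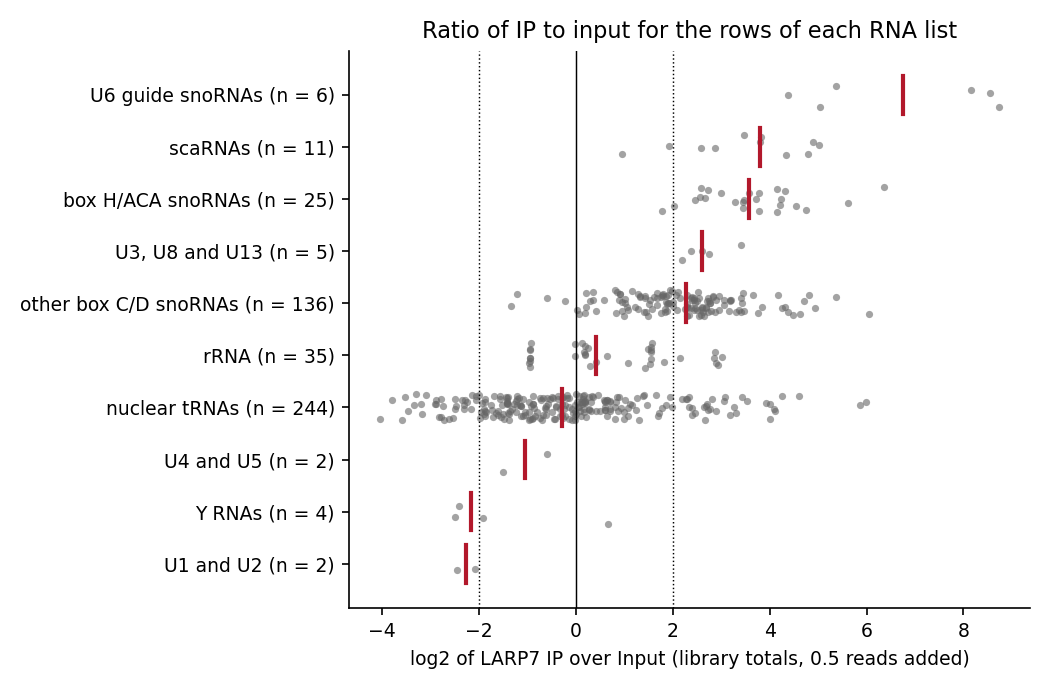
Log2 ratio of LARP7 IP to Input (x axis, library totals with 0.5 reads added) for the rows of each fixed RNA list with at least 50 reads; each grey point is a row, the red bar is the median of the list, the solid line marks equal shares and the dotted lines 4-fold differences. Medians run from 6.76 for the U6 guide snoRNAs, 3.81 for scaRNAs and 3.58 for H/ACA snoRNAs to -2.28 for U1 and U2; the vertical scatter has no meaning.

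The rows named for the other spliceosomal snRNAs, 5S rRNA and RPPH1 and 3 of the 4 rows named for Y RNAs were lower in the IP. The U2 row was 5.51-fold lower in the IP (5.31 to 5.72) and the U1 row 4.26-fold lower (4.09 to 4.44). The rows named for the tri-snRNP partners of U6 were lower by less, the U5 row 2.84-fold (2.74 to 2.95) and the U4 row 1.52-fold (1.40 to 1.64). The 5S rRNA row was 4.16-fold lower (3.95 to 4.39) and RPPH1, the RNA of RNase P, 3.52-fold lower (2.84 to 4.41). Among the rows named for Y RNAs, which bind Ro60, HY3 was 5.70-fold lower (3.62 to 9.33), HY1 5.35-fold lower (4.25 to 6.79) and HY5 3.83-fold lower (2.72 to 5.48). The HY4 row was 1.58-fold higher (1.44 to 1.73), a direction that turned with the total taken without rRNA. The median of the 4 Y RNA rows was -2.17 on the log2 scale while their summed ratio was only 0.910, because HY4 held most of their reads. The vault RNA rows VTRNA1-1, VTRNA1-2 and VTRNA1-3 (26 and 18 reads in all) and the 7SL row (2 and 3 reads), the RNA of the signal recognition particle, were under the filter and were not compared. No row carried a name from the lists of 7SK copies, single U6 genes, minor spliceosome snRNAs, telomerase RNA, mitochondrial tRNAs or microRNAs. Since rows with an Ensembl ID alone were not matched to the lists, such RNAs may still have been counted there.

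Of 244 nuclear tRNA rows past the filter, 32 were at least 4-fold higher, 32 at least 4-fold lower and 180 between. That balance depended on the library total: with the total taken without rRNA, 17 were at least 4-fold higher and 77 at least 4-fold lower. Their median log2 ratio was -0.29, at percentile 0 of the matched random lists, while their summed ratio was 1.15 (1.138 to 1.161). The opposite signs came from a single row: without tRNA-Gly-CCC-chr1-135, which went from 507 to 32437 reads (58.1-fold, 53.2 to 63.5), the summed tRNA reads were 1.35-fold lower in the IP (1.33 to 1.36), and the summed ratio with it also turned below 1 with TMM factors, with repeated rows counted once and with the total taken without rRNA. Among tRNA rows with at least 200 reads, tRNA-Ala-GCY was 65.6-fold higher (39.6 to 118) and tRNA-Gly-TCC-2-5 was 24.7-fold higher (16.4 to 38.8). The name tRNA-Ala-GCY carries no gene number, and whether that row counts genes or dispersed copies is not given in the sources used here. tRNA-Val-TAC-1-2 was 9.91-fold lower (7.56 to 13.2), tRNA-Ala-AGC-3-1 6.94-fold lower (5.81 to 8.35) and tRNA-Glu-CTC-1-1 4.42-fold lower (3.52 to 5.59). The abundant tRNA-Gln-CTG-1-4 was 2.68-fold lower (2.55 to 2.82). Near-identical tRNA genes share reads, so single rows are uncertain.

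Of 35 rRNA rows past the filter, 6 were at least 4-fold higher and 29 lay between. The precursor rows RNA45SN1, RNA45SN5 and RNA45SN3 were 8.12-fold, 7.67-fold and 7.44-fold higher, and the 5 precursor rows together went from 1978 to 16474 reads. The sixth row at least 4-fold higher was RNA18SP at 4.43-fold (4.00 to 4.93), named after its values were seen. The mature 5.8S rows, the most abundant named rRNA rows, went the other way, with RNA5-8SN4 1.95-fold lower (1.93 to 1.97) and RNA5-8SN1 1.92-fold lower (1.90 to 1.94); RNA5-8SP8, RNA5-8SN2, RNA5-8SN3 and RNA5-8SP10 lay between them or within their intervals. The list's median was 0.41 and its summed ratio 0.577, which differ in sign, and the median turned to -0.42 with the total taken without rRNA. Each of these rRNA genes has near-identical copies in the table, and the 5.8S rows were counted a second time under Ensembl IDs.

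Rows known only by an Ensembl transcript ID held 97 of the 284 rows at least 4-fold higher and 79 of the 118 lower. ENST00000636484 and ENST00000365328, joined in a single row, went from 54 to 25296 reads, 425-fold higher (326 to 566), close to SNORD8. SNORD8 did not have the highest ratio of all rows, since ENST00000365188 went from 1 to 1245 reads, 1131-fold higher (203 to 44689). Among the 15 rows with the highest log2 ratios and at least 200 reads, only SNORD8, SNORD94 and the 7SK row had names. The others, most of the 15, carried Ensembl IDs alone. ENST00000387459 held 4.41% of the Input (141796 reads) and 13864 IP reads, 11.3-fold lower (11.1 to 11.5), and ENST00000387429 was 38.9-fold lower (21.5 to 78.7). These IDs were chosen after their values were seen, and the tables used here do not pair them with gene names.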

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

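In this part, the tests of few Input reads, of snoRNAs of like length and of bulk recovery were chosen after the results were seen.

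The row that joins ENST00000636484 and ENST00000365328 has no gene name here, so whether its RNA belongs to a fixed list is not known. It went from 54 to 25296 reads, 425-fold higher in the IP (326 to 566). Rows named snoID, which none of the fixed lists covers, were summed and went from 297 to 2274 reads, 6.95-fold higher (6.16 to 7.87). Reads on the repeat family FordPrefect, a DNA transposon family, went from 690 to 6416, 8.44-fold higher (7.80 to 9.15).

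The U6 guide snoRNAs stood above the other box C/D snoRNAs. The median of the lower limits of the exact 95% counting intervals of the 6 members was 4.64 (log2). That lay above 3.46, the 90th percentile of the ratios of the 141 others. It cannot exclude few Input reads for SNORD7, SNORD67 and SNORD9, since such rows pass the filter only with far more IP reads. Their log2 ratios were 5.37, 5.04 and 5.56 (at the bound). The others with 2 to 6 Input reads had 5.37 (SNORD16), 4.94, 4.82, 4.31, 3.40 and 3.17. SNORD8 and SNORD94 had lower limits of 380-fold and 201-fold, above the highest other, SNORD14C at 68.8-fold. A straight line on annotated length moved the values by only -0.014 between the median lengths of members (110 nt) and others (76 nt), so the residual of 4.59 it left tests nothing. Among 17 others of 97 to 148 nt, the range of the members, the 90th percentile was 4.34 against a member median of 5.58 with SNORD9 at its bound, which argues against length as the whole cause, although SNORD16, within that range, reached 5.37. A candidate explanation is that LARP7 is held with the U6 guide snoRNAs, directly or through U6. However, SNORD7, SNORD67 and SNORD9 rest on 3, 3 and 0 Input reads, and a difference in ligation or recovery between the extractions stays open.

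The snoRNA and scaRNA lists were higher in the IP. The rRNA share of the library total did not account for this, because the lowest of the 3 list medians was still 1.48 (log2) with the total taken without rRNA. Against bulk recovery of nuclear small RNA-protein particles stand the rows U1, U2, U4 and U5, the highest of which had a log2 ratio of -0.60, and RPPH1, 3.52-fold lower (2.84 to 4.41), but whether the U rows count genes or dispersed copies is not given and RPPH1 is a single RNA, so recovery of part of these particles stays open. Binding to beads or serum without LARP7, or the different extraction method, cannot be told apart from binding to LARP7, since 0 of the libraries analysed here came from a control immunoprecipitation. A general affinity for snoRNA particles stays open for each list.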

How the results depend on the processing

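The totals with repeated rows counted once, the totals without rRNA, and the medians and percentiles with 0 reads at the floor were chosen after the data were seen. Against the library total, scalings moved all log2 ratios by 0.139 (DESeq2, whose size factors were 1 in both libraries), -0.319 (TMM), 0.0001 (without 7SK and U6), -0.283 (repeated rows once) and -0.836 (without rRNA). Of the alternative values for the main results, 68 stayed within their interval or within 1.5 times the main count, 44 moved beyond it in the same direction and 1, the rRNA median, changed sign beyond it. Among the 68, the total without 7SK and U6 could scarcely change a value, and leaving out the interval kept 284 and 118 rows, so these entries say little of stability. Of the 68, the log2 ratio of the U6 row, 0.43, also changed sign, to -0.41 without rRNA in the total, within its counting interval; the cause was not tested unless the setting's construction gives it. Rows at least 4-fold higher and lower numbered 570 and 201 with at least 10 reads and 754 and 218 without a filter, as more rows entered, and 153 were higher with at least 200 reads. At 8-fold they numbered 181 and 31, at 2-fold 251 were lower, and without rRNA in the total 228 were lower. The 7SK log2 ratio, 9.04 with 0.5 reads added, was 5.74 with 5 reads added, since it has 0 Input reads. The U6 guide median, 6.76, was 5.92 without rRNA in the total, 6.17 and 4.58 with 1 and 5 reads added, 8.54 with at least 200 reads, which keeps 3 members, and 5.58 with 0 reads at the floor. The median of all box C/D snoRNAs was 2.46 (DESeq2), 2.00 (TMM), 2.04 (repeated rows once), 1.48 (without rRNA) and 2.47 (at least 200 reads). That of H/ACA snoRNAs was 3.26 (TMM), 3.29 (repeated rows once), 2.74 (without rRNA), 3.18 (5 reads added) and 2.92 (at least 10 reads), and that of scaRNAs 2.97, 3.13 and 2.99 in the last 3 of these settings. The nuclear tRNA median was -0.15 (DESeq2), -0.61 (TMM), -0.58 (repeated rows once) and -1.13 (without rRNA). The rRNA median was 0.093 (TMM) and 0.13 (repeated rows once) and changed sign to -0.42 without rRNA in the total, the cause being the shift itself. With repeated rows counted once, Input and IP shares were 9.05% and 51.8% for box C/D snoRNAs, 0.0170% and 4.87% for U6 guides, 0.0693% and 1.07% for H/ACA snoRNAs, 3.23% and 3.05% for nuclear tRNAs, whose order turned, and 47.3% and 22.4% for rRNA. The U6 guide median stayed at percentile 99.97 to 100 under every matching tried. Scaling to microRNAs, the sum of 7SK and its copies, and the 5 transcribed U6 genes alone were not run, since no row carries the name of a microRNA, a 7SK copy or a single U6 gene. No paired analysis was possible because there is 1 library per group, and no replicate could be left out. Depth limits the RNAs with 0 to 3 Input reads and the U6 row, with 30 reads in all.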

Other observations

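The tRNA groups went both ways by anticodon, a split made after the data were seen. Of 41 anticodons with at least 200 reads, 6 were at least 4-fold higher in the IP: Gly-CAC at 15.9-fold (11.4 to 22.9), Gly-TCC at 9.67-fold (8.52 to 11.01), Gln-TTG at 5.52-fold (5.01 to 6.08), Gly-CCC at 5.14-fold (5.01 to 5.27), Ser-TGA at 4.52-fold (3.35 to 6.22) and Phe-GAA at 4.27-fold (3.53 to 5.21). With the total taken without rRNA 2 of these, Gly-CAC and Gly-TCC, were at least 4-fold higher and 8 anticodons at least 4-fold lower. Asp-GTC was 5.21-fold lower (4.41 to 6.19), His-GTG 2.77-fold lower and Gln-CTG, the most abundant tRNA group of the Input with 30462 reads, 2.60-fold lower (2.55 to 2.65). The glycine tRNAs did not move together, since Gly-GCC was 2.57-fold lower (2.41 to 2.74). Gly-CCC without tRNA-Gly-CCC-chr1-135 had a ratio of only 0.975 (0.943 to 1.01).

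Among the rRNA rows, the 5 RNA45S rows were together 7.56-fold higher (7.22 to 7.93), the 10 RNA18S rows 3.00-fold higher (2.93 to 3.08), the 6 RNA28S rows 1.13-fold higher (1.11 to 1.15) and the 14 RNA5-8S rows 1.89-fold lower; the RNA28S direction turned with TMM, with repeated rows counted once and with the total without rRNA. Reads on Alu repeats went from 1003 to 4863, 4.403-fold higher (4.11 to 4.72), of which AluJr alone had 120 and 2159 reads (16.3-fold, 13.6 to 19.8). Summed L1 repeats were 1.55-fold lower (1.50 to 1.61), while the median log2 ratio of the L1 rows with at least 50 reads was 0.24, of the opposite sign, which turned with the same 3 scalings as RNA28S. snoID_0762, the highest of the 13 snoID rows past the filter, went from 8 to 447 reads (50.7-fold, 25.5 to 118). These groups were chosen after their values were seen.

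Box C/D snoRNAs outside the U6 guides differed widely, from SNORD136, 2.34-fold lower, to SNORD14C, 68.8-fold higher, among those with at least 200 reads. Most are processed from introns of a host gene, so a hypothesis was that snoRNAs of the same host share their ratio. Over 89 of these snoRNAs with at least 50 reads, within 29 genes, the SD of the log2 ratio within genes was 1.19, against a median of 1.18 and a 5th percentile of 1.07 with gene labels shuffled 10000 times (one-sided permutation p = 0.559). In GAS5, which holds 10 of the 89, log2 ratios ran from 0.35 to 3.18. The host gene thus did not account for the spread as a whole, while a small share of it is not excluded.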
